A study of Rattus norvegicus with 8 samples.

How the data were processed

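Total RNA from snap-frozen livers of 8 male Fischer 344 rats was hybridised to Affymetrix Rat Genome U34 arrays (version A), 1 array per rat, with 4 rats given D3T and 4 given vehicle. Groups and replicate numbers were taken from the sample titles, and the series design states 4 rats per group. All 8 arrays were used, as 1 table with a column per array. The deposited values are linear signal intensities, 1 per probe set and array, and per the submitters' processing notes they were made with MAS5, the Affymetrix algorithm that summarises the probe pairs of a probe set. The version, scaling target, detection calls and filters of that step are not given in the sources used here. From the values themselves, every intensity was above 0 and the 2% trimmed mean of each array lay within 1 of the others, the lowest at 500.8, so the arrays had been scaled to a common level before deposit. An intensity has no count behind it, so no depth can be stated, and the number of arrays limits the precision.

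Each array was rescaled to a 2% trimmed mean of 500, values below the 20th percentile of all values (a signal of 20.3) were raised to that floor, and log2 was taken. After 59 control probe sets were left out of 8799, the 60% of the remaining 8740 with the highest mean log2 signal over all arrays, blind to group, were tested, which gave 5244 probe sets. The comparison was fitted with limma version 3.58.1 in R version 4.3.3 (lmFit and eBayes with an intensity trend), and Benjamini-Hochberg adjusted p under 0.05 was the threshold. Fold changes are ratios of geometric means of the floored signals, so they understate the change of probe sets near the floor. The median residual SD was 0.31 on the log2 scale. Means and SDs of signals are on the linear scale over the 4 arrays of a group.

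Gene names came from the platform's annotation table, of which 7006 probe sets were matched to 1 gene symbol, 308 to several and 1426 to none. The identifiers of 6985 of the 7006 were found in the NCBI RefSeq gene table of the rat assembly GRCr8, and none of these had a newer symbol. The names covered 4736 genes. No gene was named from a probe set with several symbols, and no genome sequence or coordinate was used. A gene was represented by its tested probe set with the highest mean signal, and disagreement in sign with its other tested probe sets is stated.

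The genes named in the text were set by a rule fixed before the data were examined. It took, per direction, the 12 genes with the largest fold change among those past the threshold whose D3T arrays all lay on one side of the vehicle arrays, and in each of 30 gene lists up to 3 members past the threshold with the largest fold change, or the brightest member where none passed. Nqo1, Gclc, Gclm, Akr7a3, Ephx1, Gstp1, Gsta2, Txnrd1, Nfe2l2, Keap1, Cyp7a1 and Alb were always included where measured. Genes named outside the rule are said to have been chosen after their values were seen. The lists, also fixed beforehand, covered detoxification, metabolism, protein and cell maintenance, secreted proteins and markers of other cell types in liver. They were tested with camera at its preset correlation of 0.01, with an estimated correlation and fry beside it, over lists with at least 3 genes tested. Measures of RNA quality and scaling per array were compared with exact two-sided permutation tests over all 70 assignments.

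Scripts were tested on simulated data with the levels and residual spread of these arrays, in which 200 of 5244 probe sets were changed for the comparison of D3T against vehicle. The fit recovered 19.4% of those changed 1.5-fold, 52.2% of those changed 2-fold and 83.3% of those changed 4-fold, and 7 of 110 calls (6.36%) were unchanged probe sets. A simulated raised list was found, and of 30 simulated lists without change 0 had a camera p under 0.05. The simulated genes were drawn independently, so this does not test lists whose genes are correlated. Alternatives were no rescaling, quantile normalization, median centring, log2 of signal plus 16 without a floor, a floor at the 40th percentile, no filter, a filter keeping the brightest 30%, no intensity trend, robust variance, array weights, the replicate number as a block, leaving out probe sets whose names mark shared sequence, the mean of a gene's probe sets, an estimated correlation and leaving out each array in turn. The actin 3'/5' ratio as a covariate was added after the data were seen.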

Results

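Liver RNA was measured in 8 male Fischer 344 rats, 4 given D3T and 4 given the vehicle alone, with 1 Affymetrix Rat Genome U34 array (version A) per rat. D3T is a dithiolethione, a class of sulfur compounds known to induce detoxification enzymes through the transcription factor encoded by Nfe2l2. The D3T rats received 0.3 mmol per kg body weight by gavage in saturated sucrose on days 1, 3 and 5, and the vehicle rats received 0.2 ml of saturated sucrose. The labels give the days for 3 of the 4 vehicle rats and name none for vehicle replicate 2. The design contains 1 comparison, D3T against vehicle, which asks which liver transcripts differ after D3T. An array gives a signal per probe set and no count, so precision was set by the number of arrays. The arrays had nearly equal 2% trimmed means, the lowest 500.8, and correlations of log2 signals between any pair of arrays ran from 0.896 to 0.962 over probe sets, which are not independent replicates. No array repeated another, since at most 31 of the 8740 non-control probe sets held identical values in any pair of arrays.

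D3T-treated livers had higher transcripts of the glutathione transferases Gsta3, Gstp1 and Gsta1, and of Akr7a3, Ephx1 and Nqo1, which act on reactive and foreign compounds, and lower transcripts of 6 of 14 cholesterol synthesis genes, a list that did not pass with an estimated correlation (adjusted p = 0.173 with an estimated correlation). Gsta3 was 53.5-fold higher, Gstp1 29.9-fold and Akr7a3 16.5-fold, whereas Insig1, a protein that restrains sterol synthesis and is itself induced by low sterol, was 4.51-fold lower. Among 5244 probe sets tested with limma, 560 passed an adjusted p of 0.05 (10.7%), of which 220 were higher and 340 lower after D3T. A change of at least 1.5-fold was found for 162 higher and 295 lower probe sets. The 4 D3T arrays lay wholly above or below the 4 vehicle arrays for 1008 probe sets, 19.2% of those tested against 2.86% by chance, and this held for 212 of the higher and 315 of the lower calls. The 560 probe sets comprised 455 matched to 1 gene, 41 matched to several and 64 with no gene name here, and at the level of 1 probe set per gene 117 genes were higher and 184 lower of 3150. The first principal component held 36.7% of the variance and separated the groups, with vehicle replicate 2 nearest to the D3T arrays. The count of changed probe sets fell to 260 without vehicle replicate 1, 240 without vehicle replicate 3, 301 without vehicle replicate 4, 279 without D3T replicate 1 and 307 without D3T replicate 4. Of the 70 named genes that passed, 41 also passed whichever array was left out, while 30 no longer passed with no filter and 20 with no intensity trend. With the actin 3'/5' ratio of each array as a covariate, an alternative added after the data were seen, 35 probe sets passed, 24 higher and 11 lower, and 58 of the 70 named genes did not.

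**Figure D1:**
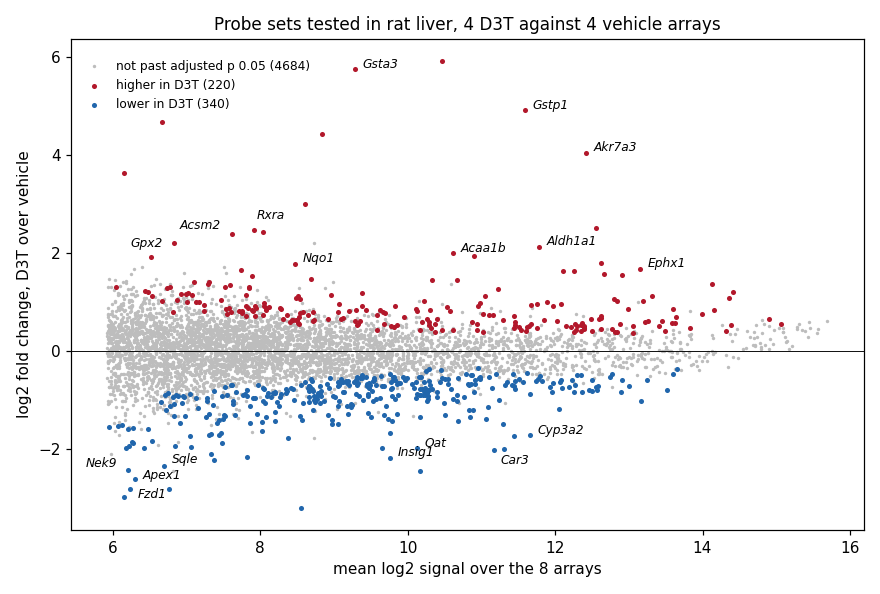
Each point is 1 of the 5244 probe sets tested, with its mean log2 signal over the 8 arrays on the horizontal axis and its log2 fold change, D3T over vehicle, on the vertical axis. Red marks the 220 probe sets higher after D3T and blue the 340 lower at an adjusted p of 0.05. Gsta3, Gstp1 and Akr7a3 stand at log2 fold changes of 5.74, 4.90 and 4.04.

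The 12 genes with the largest rises were Gsta3, Gstp1, Akr7a3, Rxra, Acsm2, Gpx2, Aldh1a1, Acaa1b, Nqo1, Ephx1, Gsta1 and Adh1c, and each was higher in 4 of 4 D3T arrays than in every vehicle array. The signal of Gsta3, an alpha-class glutathione transferase, was 91.4 ± 35.4 (SD, n = 4) in vehicle and 4587 ± 740.4 after D3T, with a log2 fold change of 5.74 ± 0.29 (SE) and an adjusted p of 1.52e-06. Gstp1, the pi-class transferase, went from 569.5 ± 76.4 to 17560 ± 5703 (log2 fold change 4.90 ± 0.21, adjusted p = 6.37e-07). Akr7a3, a reductase of aflatoxin aldehydes, went from 1371 ± 290 to 22570 ± 4453 (4.04 ± 0.19 on the log2 scale, adjusted p = 7.98e-07). The microsomal epoxide hydrolase gene Ephx1 was 3.19-fold higher (adjusted p = 8.31e-06) and the quinone reductase gene Nqo1 3.44-fold higher (adjusted p = 0.00115). Rxra, encoding a nuclear receptor, was 5.55-fold higher with a large error (2.47 ± 0.43 on the log2 scale). Acsm2, an acyl-CoA synthetase, was 5.25-fold higher, Gpx2, a glutathione peroxidase, 4.61-fold, Aldh1a1, a retinaldehyde dehydrogenase, 4.38-fold, and Acaa1b, a peroxisomal thiolase, 3.98-fold. Gsta1 and the alcohol dehydrogenase gene Adh1c were 2.98-fold and 2.95-fold higher. All 3 probe sets of Gsta3, both of Gstp1, all 3 of Gsta1 and both of Adh1c passed in the same direction. The probe sets of Gsta1, Gstp1, Akr7a3 and Nqo1 and the one chosen for Gsta3 have names that mark shared sequence. Their signal may therefore not come from the named gene alone. Such names also mark the probe sets given below for Apex1, Dnase1l3, Cyp3a2, Cyp1a2 and Sult2a1, among others. Without probe sets marked in this way, 43 of the 70 named genes that passed were still tested, and 5 of these lost their calls. The other probe sets of Gsta3 rose at least 12.3-fold and 25.3-fold, with all 4 vehicle arrays at the floor, and the other one of Gstp1 rose 59.9-fold. Acsm2 no longer passed without D3T replicate 4 (adjusted p = 0.0512), with no filter (0.0917) or with the actin covariate (0.257), and its rise was 3.34-fold without vehicle replicate 2. Neither with no filter (adjusted p = 0.0528) nor with the actin covariate (0.131) did Rxra pass. Gpx2, Nqo1 and Adh1c also lost their calls with the actin covariate (adjusted p = 0.188, 0.0802 and 0.0774).

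**Figure D2:**
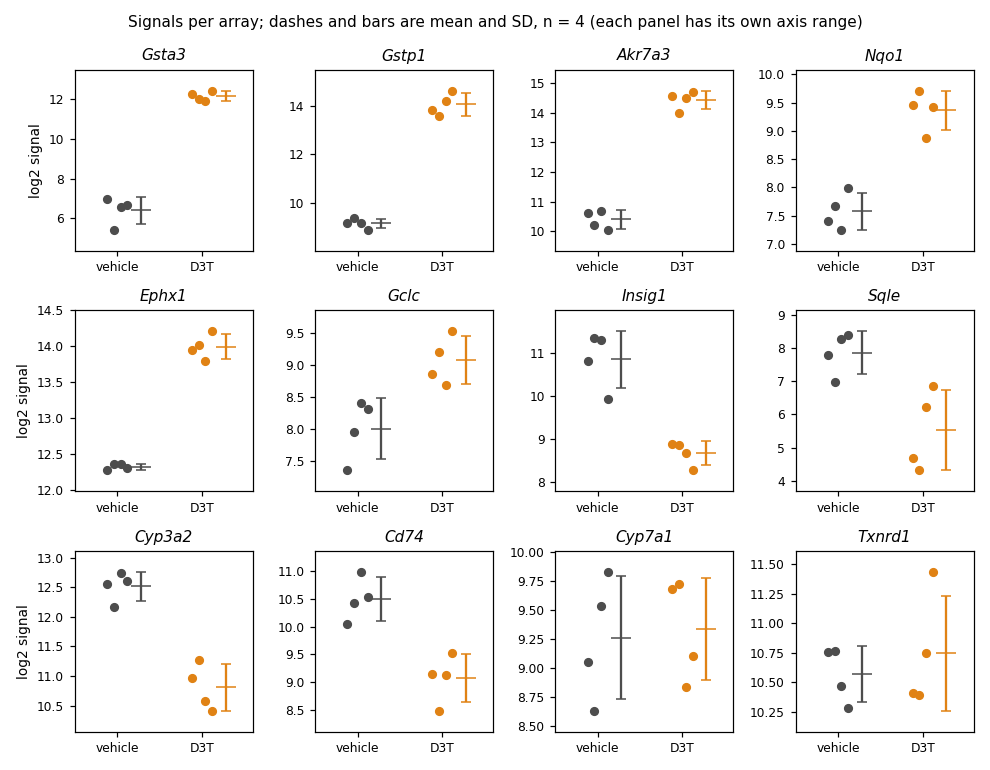
Log2 signals of 12 named genes in each of the 4 vehicle and 4 D3T arrays, with dashes and bars for the mean and SD and a separate axis range per gene. The D3T arrays of Gsta3 lie between 11.92 and 12.42, above every vehicle array, whereas the groups overlap for Cyp7a1 and Txnrd1.

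By the probe set chosen for each gene, the 12 genes with the largest falls were Fzd1, Apex1, Nek9, Sqle, Insig1, Dnase1l3, Car3, Oat, Tln1, Atxn3, Ulk2 and Cyba. Fzd1, a Wnt receptor, was at least 7.03-fold lower, since 3 of its 4 D3T arrays lay at the floor and D3T replicate 4 stood above them. Apex1, an endonuclease of base excision repair, was 6.12-fold lower (adjusted p = 0.00146) and the kinase gene Nek9 5.33-fold lower (adjusted p = 0.00243). Insig1 went from 1974 ± 756.8 (SD, n = 4) to 413.6 ± 74.9, with an adjusted p of 0.00161, and squalene epoxidase (Sqle) from 248.4 ± 95.7 to 55.8 ± 48.9 with 1 D3T array at the floor (adjusted p = 0.0271). Car3, an abundant hepatocyte carbonic anhydrase, was 4.05-fold lower (4694 ± 858.9 against 1178 ± 342.3, adjusted p = 0.000253). Oat, which degrades ornithine, was 3.94-fold lower and Cyba, a subunit of the NADPH oxidase of phagocytes, 3.68-fold lower, from 343.7 ± 10.7 to 93.4 ± 3.73. Dnase1l3, a secreted nuclease, was 4.45-fold lower, the cytoskeletal gene Tln1 3.88-fold, the deubiquitinase gene Atxn3 3.83-fold and the autophagy kinase gene Ulk2 3.81-fold. For Atxn3 the other probe set tested had the opposite sign (0.52 on the log2 scale, not past the threshold), and D3T replicate 2 lay below the other D3T arrays. With the floor at the 40th percentile the log2 fold changes were smaller, at -1.56 for Fzd1, -1.59 for Apex1, -1.40 for Nek9, -1.58 for Sqle and -1.18 for Atxn3, and all 5 still passed. With the actin covariate those of Fzd1 and Dnase1l3 were larger, at -3.83 and -3.44, and no longer passed (adjusted p = 0.0512 and 0.0777). Nek9, Sqle, Insig1, Oat, Tln1, Atxn3 and Ulk2 did not pass with it either (adjusted p from 0.0774 for Insig1 to 0.310 for Tln1). Sqle, Dnase1l3, Tln1 and Ulk2 passed in 4, 4, 6 and 2 of 8 fits without 1 array, with adjusted p up to 0.0815, 0.0917, 0.0558 and 0.0756. With no filter none of these passed (adjusted p = 0.105, 0.136, 0.0721 and 0.0987). With no intensity trend Sqle (0.0506) and Dnase1l3 (0.0683) did not pass. With the replicate number as a block Dnase1l3 (0.0549) and Tln1 (0.0542) did not.

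Of 22 genes of glutathione synthesis and conjugation, 13 were higher and none lower (14 higher when adjusted over the list alone), with a median log2 fold change of 0.55. The list passed camera with an adjusted p of 1.51e-09, and not with an estimated correlation (adjusted p = 0.0921 with an estimated correlation). Gsta3, Gstp1 and Gpx2 led the list. Gclc, the catalytic subunit of the enzyme that limits glutathione synthesis, was 2.10-fold higher (adjusted p = 0.0282, but 0.0772 in the least favourable fit without 1 array, 0.0926 with no filter and 0.0548 with no intensity trend). With the actin covariate it was 1.36-fold higher and did not pass (adjusted p = 0.599). Its partner subunit gene Gclm was 1.32-fold higher without passing (adjusted p = 0.0913), with 1 of its 3 probe sets in the opposite direction. A pair of probe sets matched to more than 1 alpha-class transferase was also higher. No tested probe set was matched to Gsta2 or to Keap1 alone.

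The list of enzymes acting on quinones, aldehydes and epoxides also holds thioredoxin and heme enzymes, namely Txnrd1, Prdx1, Hmox1 and Blvra among those tested. It included 6 higher of 15 and none lower, the same count adjusted over the list alone. The median was 0.27 (camera adjusted p = 0.000103, and adjusted p = 0.281 with an estimated correlation). Akr7a3, Aldh1a1 and Nqo1 had the largest changes. Thioredoxin reductase (Txnrd1) was measured at 1535 ± 242.8 in vehicle and 1799 ± 672.6 after D3T and did not pass (adjusted p = 0.624). Nfe2l2 itself had a log2 fold change of -0.73 ± 0.37 and did not pass (adjusted p = 0.219), nor with the actin covariate (-1.38, adjusted p = 0.290).

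Genes for conjugation with glucuronic acid and with sulfate changed in both directions. Among 16 genes for UDP-glucuronosyltransferases, sulfotransferases and their cofactors, 5 were higher and 4 lower (7 and 5 adjusted over the list alone). Ugt2b7 was 2.46-fold higher from a low level, a call close to the threshold (adjusted p = 0.0497). It passed in 0 of the 7 fits without 1 array in which it was tested (adjusted p up to 0.113). With the higher floor its log2 fold change was 0.68 (adjusted p = 0.0753). Over all 19 alternative settings it passed in 4. Sult2a1, a steroid sulfotransferase, was 2.59-fold lower and Papss2, which makes the sulfate donor, 2.53-fold lower. All 3 probe sets of Sult2a1 passed as lower, the others at 2.02-fold and 5.47-fold. Of 9 probe sets matched to several members of the UGT1A cluster, and so to no single gene, 8 were higher. The list as a whole did not pass (median 0.18, camera adjusted p = 0.571).

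The list of cytochrome P450 genes for foreign compounds, which also holds their partners Cyb5a, Cyb5r3 and Por, showed 3 higher and 3 lower of 27 (4 and 5 adjusted over the list alone). The 3 higher, chosen after their values were seen, were Cyp2b2, Cyp2a1 and Cyb5a. Cyp3a2 was 3.28-fold lower, from 5931 ± 955.5 (SD, n = 4) to 1841 ± 505.4, Cyp1a2 2.29-fold lower and Cyp3a9 2.01-fold lower. All 3 probe sets of Cyp1a2 passed as lower, the others at 2.69-fold and 9.10-fold. The list had a median of 0.01, a mean of -0.12 and a downward test that did not pass (camera adjusted p = 0.972). Of 9 hepatic transporter genes 2 were lower and none higher, also 2 adjusted over the list alone. The list median was -0.35 (camera adjusted p = 0.0122, and adjusted p = 0.198 with an estimated correlation). The canalicular export pump genes Abcc2 and Abcb4 were 1.91-fold and 1.58-fold lower. The list median lay within the range of random lists matched on level, at percentile 3.23 where 95% ran from -0.38 to 0.30. Abcb4 lost its call in some fits without 1 array (adjusted p up to 0.0624). Among 4 genes of NADPH supply, transketolase (Tkt) was higher by a log2 fold change of 0.59 and the other 3 did not pass (1 higher and 1 lower adjusted over the list alone, median 0.18, camera adjusted p = 0.796). Tkt passed in 3 of 8 fits without 1 array (adjusted p up to 0.0759). None of 8 iron handling genes passed with limma, over all probe sets or adjusted over the list alone, and the median was 0.03 (camera adjusted p = 0.972). Its brightest member, hemopexin (Hpx), had a log2 fold change of 0.04 ± 0.14, which became -0.28 with quantile normalization. Both probe sets matched to copies of the ferritin light chain were higher.

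Of 14 cholesterol synthesis genes 6 were lower and none higher (9 lower adjusted over the list alone), with a median of -0.57. The list passed camera with an adjusted p of 9.87e-06, and not with an estimated correlation (adjusted p = 0.173 with an estimated correlation). All 14 had negative fold changes. Sqle, Insig1 and Msmo1, a sterol methyl oxidase, were 5.04-fold, 4.51-fold and 2.61-fold lower. In fatty acid synthesis only the elongase gene Elovl5 passed, 1.74-fold lower, among 10 genes (also 1 adjusted over the list alone, median -0.20, camera adjusted p = 0.470). In fatty acid oxidation 2 genes were higher and 3 lower of 25 (2 and 4 adjusted over the list alone, median -0.10, camera adjusted p = 0.796). Acaa1b was 3.98-fold higher, whereas the fatty acid hydroxylase gene Cyp4a1 was 1.68-fold lower, with 1 of its 3 probe sets in the opposite direction, and the dehydrogenase gene Acadl 1.49-fold lower, with overlapping groups of arrays. Cyp4a1 and Acadl passed in 4 and 2 of 8 fits without 1 array (adjusted p up to 0.0714 and 0.116). In bile acid synthesis Akr1d1 was 1.52-fold higher among 8 genes, with 1 higher and 4 lower adjusted over the list alone (median -0.28, camera adjusted p = 0.470). Cyp7a1, the rate-limiting enzyme of that pathway, was measured at 646.1 ± 227.4 (SD, n = 4) in vehicle and 669.4 ± 195.4 after D3T (adjusted p = 0.878).

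Among 26 genes of the urea cycle and amino acid breakdown, 4 were lower and none higher, also 4 adjusted over the list alone. Oat was 3.94-fold lower, Kynu, of tryptophan breakdown, 1.99-fold lower with overlapping groups of arrays and Gnmt, a glycine methyltransferase, 1.67-fold lower, while the list did not pass (median -0.01, camera adjusted p = 0.756). In glycolysis and gluconeogenesis 1 of 18 genes passed, Pgam1, at 1.43-fold higher (2 higher and 3 lower adjusted over the list alone). The median of that list was 0.02, the mean -0.07 and its downward test had a camera adjusted p of 0.972. Kynu and Pgam1 each passed in 3 of 8 fits without 1 array (adjusted p up to 0.0712 and 0.0787).

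The proteasome list had a median of -0.29 over 26 genes (camera adjusted p = 0.00675, and adjusted p = 0.392 with an estimated correlation). A single member passed as lower, Psma6 at 1.38-fold, and a single one as higher, Psmb4 at 1.96-fold, with 5 lower and 1 higher adjusted over the list alone. For Psmb4, 1 of 3 probe sets had the opposite sign and vehicle replicate 2 stood above the other vehicle arrays. Psma6 passed in 2 of 8 fits without 1 array (adjusted p up to 0.113). The list lost its call with the actin 3'/5' ratio as a covariate (adjusted p = 0.102). Of 20 chaperone and endoplasmic reticulum stress genes, 1 was higher and 3 lower, the same counts adjusted over the list alone. Hsph1, Canx and Pdia4 were 1.88-fold, 1.72-fold and 1.59-fold lower. Canx and Pdia4 passed in 2 and 3 of 8 fits without 1 array (adjusted p up to 0.106 and 0.0839). For Canx, 1 of 5 probe sets had the opposite sign and D3T replicate 2 lay apart from the other D3T arrays. The list median was 0.18 and its upward test did not pass (camera adjusted p = 0.628).

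Of 42 ribosomal protein genes 7 were higher and 1 lower (13 and 1 adjusted over the list alone), with 33 positive fold changes and a median of 0.21. The list had a camera adjusted p of 0.000324, and an adjusted p = 0.392 with an estimated correlation. The changes of single genes were small apart from Rpl19l4, a copy of a ribosomal protein gene, at 2.31-fold lower. Rps24 was 1.52-fold and Rpl27a 1.44-fold higher, and Rps24 lost its call in some fits without 1 array (adjusted p up to 0.0720). Among 53 genes of the mitochondrial respiratory chain Ndufv2 passed at 1.35-fold higher, and none adjusted over the list alone. Ndufv2 passed in 1 of 8 fits without 1 array (adjusted p up to 0.121). The list had a median of -0.04, a mean of 0.01 and a downward camera test with an adjusted p of 0.972.

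Cell cycle and DNA replication genes included 4 higher and 1 lower of 17 (5 and 1 adjusted over the list alone). Top2a, a topoisomerase of dividing cells, was 1.89-fold higher and Cdc20, a mitotic regulator, 1.83-fold higher, whereas Ccnd1, a cyclin of the entry into the cycle, was 2.17-fold lower. For Ccnd1, 1 of 4 probe sets had the opposite sign, and for Top2a vehicle replicate 2 lay below the other vehicle arrays. The list did not pass (median 0.34, camera adjusted p = 0.130) except without D3T replicate 2 (adjusted p = 0.0468). Top2a and Cdc20 passed in 3 and 1 of 8 fits without 1 array (adjusted p up to 0.0550 and 0.120). Of 5 p53 targets and growth arrest genes Mdm2 passed at 1.67-fold higher, also the only one adjusted over the list alone (median 0.30, camera adjusted p = 0.470). Mdm2 passed in 3 of 8 fits without 1 array (adjusted p up to 0.0828). None of 9 immediate early genes passed with limma, over all probe sets or adjusted over the list alone. The brightest, Zfp36, had a log2 fold change of -0.39 ± 0.13 (adjusted p = 0.0813) with 1 of its 2 probe sets in the opposite direction. The median of that list was 0.18, the mean -0.004 and its upward test had a camera adjusted p of 0.972.

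The list of male-predominant genes, those more abundant in male than in female rat liver, included 4 lower and none higher of 10 (5 lower adjusted over the list alone). It also holds general growth hormone and insulin-like growth factor genes such as Ghr and Igfals, so its fall is not one of male-predominant genes alone. The list median was -0.49 (camera adjusted p = 0.0173, and adjusted p = 0.281 with an estimated correlation). Cyp3a2 was 3.28-fold lower, and Igfals and Ghr, which belong to growth hormone and insulin-like growth factor signalling, were 1.85-fold and 1.79-fold lower. The list call ended with a stricter filter (adjusted p = 0.0529) and with the actin 3'/5' ratio as a covariate, which took the median to -0.16 (adjusted p = 0.261).

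Acute phase genes included 2 higher and 5 lower of 18 (2 and 7 adjusted over the list alone). Fibrinogen beta (Fgb) went from 15640 ± 2179 (SD, n = 4) to 9071 ± 1897 and C-reactive protein (Crp) from 7494 ± 1213 to 4340 ± 631.7, 1.74-fold and 1.72-fold lower, while Cd14 was 1.74-fold higher. D3T replicate 2 lay apart from the other D3T arrays for Crp. The list median was -0.19 and the list did not pass (camera adjusted p = 0.129), but it passed downward with quantile normalization (median -0.32, adjusted p = 0.000228), with the mean of a gene's probe sets (adjusted p = 0.0478), without vehicle replicate 3 (adjusted p = 0.0447) and without D3T replicate 3 (adjusted p = 0.0161). Among 22 genes for proteins secreted by hepatocytes 3 were lower and none higher, also 3 adjusted over the list alone. Afm, an albumin relative, was 2.02-fold lower, coagulation factor F10 1.61-fold and the apolipoprotein gene Apoa4 1.51-fold lower. Albumin (Alb) was measured at 39140 ± 8877 (SD, n = 4) in vehicle and 53450 ± 8971 after D3T and did not pass (adjusted p = 0.106). The list median was 0.13 (camera adjusted p = 0.796) and became -0.15 with quantile normalization, where the list passed in the downward direction, while with the actin covariate it was 0.28 and passed upward (adjusted p = 0.00790). F10 and Apoa4 passed in 5 and 2 of 8 fits without 1 array (adjusted p up to 0.0599 and 0.120).

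Markers of macrophages and Kupffer cells, the resident macrophages of the liver, included 5 lower and 1 higher of 10 (7 and 2 adjusted over the list alone), with a median of -0.76. The list had a camera adjusted p of 0.0173, and an adjusted p = 0.281 with an estimated correlation. Cd74, the invariant chain of antigen presentation, went from 1482 ± 406.2 (SD, n = 4) to 555.6 ± 156, 2.68-fold lower. Aif1 was 2.13-fold lower, with 1 of 3 probe sets in the opposite direction, and the Fc receptor gene Fcgr2b 1.88-fold lower, with vehicle replicate 4 apart from the other vehicle arrays. The member that rose was Cd14, at 1.74-fold, which hepatocytes also make. The list call was also lost with a stricter filter (adjusted p = 0.0515) and without vehicle replicate 2 (adjusted p = 0.0527), and those of Aif1 and Fcgr2b in some fits without 1 array (adjusted p up to 0.0534 and 0.0681).

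Markers of the other cell types did not pass as lists by camera in the main setting. Of 15 stellate cell and fibroblast markers 2 were lower and none higher (4 lower adjusted over the list alone, median -0.26, camera adjusted p = 0.160, and 0.0441 with the mean of a gene's probe sets), namely Col3a1 at 1.86-fold and Mgp at 1.64-fold, both with overlapping groups of arrays. For Mgp, vehicle replicate 2 lay below the other vehicle arrays. Of 7 endothelial markers Lyve1 was 1.74-fold lower, also the only one adjusted over the list alone, with a list median of 0.02, a mean of -0.05 and a downward test that did not pass (camera adjusted p = 0.972). Col3a1, Mgp and Lyve1 passed in 2, 2 and 1 of 8 fits without 1 array (adjusted p up to 0.111, 0.109 and 0.121). None of 6 bile duct markers passed with limma, over all probe sets or adjusted over the list alone (median -0.25, camera adjusted p = 0.879), and Krt18 had a log2 fold change of -0.32 ± 0.16. None of 4 red blood cell markers passed over all probe sets and 2 were lower adjusted over the list alone (median -0.29, camera adjusted p = 0.470), with beta-globin (Hbb) at -0.51 ± 0.16. None of 6 lymphocyte and natural killer cell markers passed either way (median 0.22, camera adjusted p = 0.328), and Lck, for which vehicle replicate 4 lay apart, had a log2 fold change of -0.05 ± 0.18. Of 8 pancreas, muscle and fat cell markers the amylase gene Amy2a3, also made in liver, was 1.56-fold lower, the only one adjusted over the list alone as well (median 0.12, camera adjusted p = 0.972). Amy2a3 passed in 2 of 8 fits without 1 array (adjusted p up to 0.110).

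**Figure D3:**
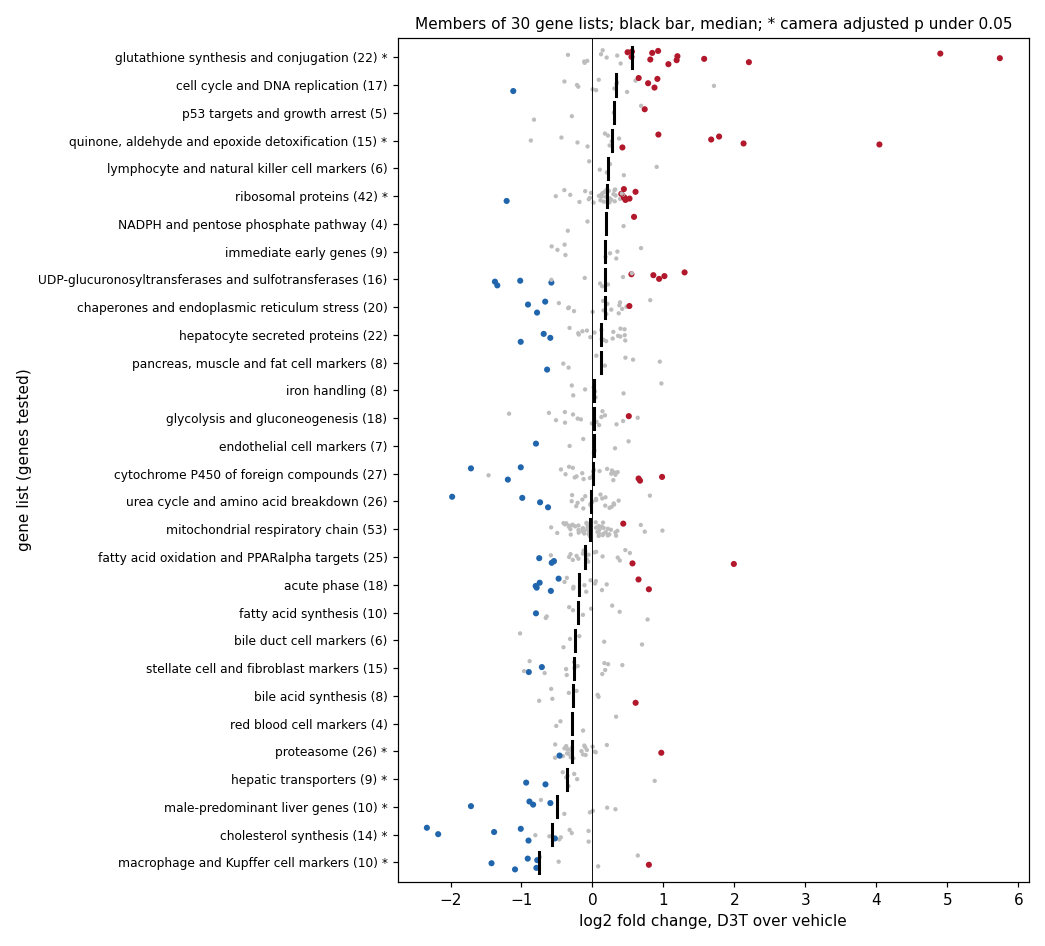
Log2 fold changes, D3T over vehicle, of the genes tested in each of 30 gene lists, ordered by list median (black bar), with the number of genes in brackets. Red points are genes higher after D3T, blue points genes lower and grey points genes not past an adjusted p of 0.05, and a star marks the 8 lists with a camera adjusted p under 0.05. Medians run from 0.55 for glutathione synthesis and conjugation to -0.76 for macrophage and Kupffer cell markers.

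In all, 8 of 30 lists passed camera, 3 of them upward and 5 downward, and none did with an estimated correlation, where the smallest adjusted p was 0.0921. Of the 8, in a check extended to all lists after the data were seen, all but the hepatic transporters had a median outside the central 95% of 10000 random lists matched on level, with percentiles of 100 for glutathione, 98.81 for quinones, aldehydes and epoxides, 99.91 for ribosomal proteins, 1.05 for the proteasome, 0.02 for the male-predominant list and 0.01 for both cholesterol synthesis and macrophage markers. The cell cycle (98.54) and acute phase (1.31) lists, which did not pass camera, also lay outside. Random draws do not keep the correlation among the genes of a list. By fry, which asks whether the genes of a list move one way on balance, 9 lists passed, among them the lymphocyte and natural killer cell markers in the upward direction (adjusted p = 0.0369), and 26 passed its test for change in either direction. Unlike camera, fry tests a list against no change and not against the other genes. Over all genes, 1536 of 5244 probe sets had an unadjusted limma p under 0.05, so a pass by fry does not set a list apart from the rest.

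No measure of RNA quality or scaling passed its test between the groups, although 4 arrays per group leave little power. The log2 ratio of 3' to 5' signal was 0.62 ± 0.07 (SD, n = 4) for beta-actin in vehicle and 0.40 ± 0.13 after D3T (exact two-sided permutation test, p = 0.0571, Benjamini-Hochberg adjusted p = 0.152 over 8 measures), where the smallest p possible was 0.0286. For Gapdh it was 0.90 ± 0.16 in vehicle and 0.65 ± 0.24 after D3T (exact permutation p = 0.114, adjusted p = 0.183), with D3T replicate 3 above the other D3T arrays. The brightest 1% of probe sets held 29.0% ± 2.70 of the signal in vehicle and 33.3% ± 2.36 after D3T (exact permutation p = 0.0571, adjusted p = 0.152). The share of probe sets at the floor was 20.3% ± 1.57 in vehicle and 19.5% ± 1.11 after D3T (exact permutation p = 0.429, adjusted p = 0.490).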

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

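The actin covariate and the tests of abundant transcripts, of a loss of macrophages and of a level trend for the ribosomal proteins were chosen after the results they measure were seen.

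In 10 of 170 groups of 4 values tested, 1 array lay far from the other 3 of its group by Dixon's ratio of gap to range, where about 8.5 are due by chance. Vehicle replicate 2 stood apart for Psmb4 (ratio 0.839), Top2a (0.856) and Mgp (0.872), and vehicle replicate 4 for Fcgr2b (0.908) and Lck (0.912). D3T replicate 2 stood apart for Atxn3 (0.916), Canx (0.838) and Crp (0.946). D3T replicate 4 stood apart for Fzd1 (ratio 1), because the other 3 D3T arrays shared the floor value. D3T replicate 3 stood apart for the Gapdh 3'/5' ratio (0.93).

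More probe sets were lower than higher after D3T, 340 against 220. The choice among the scalings tried does not account for this, since 41.4% of calls were higher with quantile normalization and 37.1% with median centring, near the 39.3% reported. These scalings assume that most probe sets are unchanged, so an error of scaling that they share was not tested. A few abundant transcripts taking signal from the rest cannot be told apart either way: the median of all tested probe sets was 0.019, but scaling to a trimmed mean leaves out the brightest probe sets and so decides nothing here. The brightest 1% held more of the signal after D3T (33.3% against 29.0%), and medians from the dimmest to the brightest of 10 levels were 0.088, 0.072, 0.046, 0.058, 0.078, 0.019, -0.075, -0.086, -0.059 and 0.09. The excess of lower calls was largest in levels 7 to 9 (57, 64 and 72 lower against 15, 20 and 37 higher), and the brightest level had 38 lower against 72 higher. RNA quality cannot be told apart from the treatment: with the actin ratio as a covariate 35 probe sets passed, 68.6% of them higher, too few to read a share from. All 340 lower calls kept their direction at a median log2 fold change of -0.82 (-0.86 before, quartiles -1.17 and -0.52 after), and their median SE widened from 0.18 to 0.28. Some fold changes shrank as well, such as those of Ghr (-0.836 to -0.365) and F10 (-0.687 to -0.287), while others grew, such as that of Fzd1 (-2.81 to -3.83). Wider errors alone therefore cannot be said to have ended the calls. An effect of D3T stays open beside these.

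Of the 9 macrophage markers other than Cd14, 5 were lower, with a median of -0.78, and the whole list did not pass with an estimated correlation (adjusted p = 0.281 with an estimated correlation). A level-dependent trend is argued against, since the list median lay at percentile 0.01 among 10000 random lists matched on level. A loss of macrophages, which would lower all markers by a common amount, cannot be told apart from a change of transcripts within them. The fold changes of the 9 differed (Cochran's Q of 62.0 with the common shift taken out, exact p = 0.0286 over the 35 splits, the smallest it can give, in place of a chi-square version calculated earlier), but this rested on C1qc and Ptprc, both chosen after their values were seen, with 95% intervals from -0.32 to 0.48 and from -0.04 to 1.32. These intervals use the residual degrees of freedom alone and are wider than the limma fit gives. In that fit Ptprc passed as higher when adjusted over the list alone. Ptprc is made by all leukocytes and C1qb, of the same complex as C1qc, fell (-1.15 to -0.43), and without C1qc and Ptprc the exact p was 0.114, so both explanations stay open.

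The 42 ribosomal protein genes had a median of 0.21, 7 of them higher and 1 lower, and their list did not pass with an estimated correlation (adjusted p = 0.392 with an estimated correlation). A level-dependent trend is argued against, since the list median lay at percentile 99.91 among 10000 random lists matched on level. With the actin ratio as a covariate the list median was 0.246 and the list still passed at the preset correlation, so the rise did not follow that ratio. The ratio is 1 measure of RNA quality and tended to be lower after D3T, so RNA quality cannot be told apart from the treatment here. A higher level after D3T may account for it as a hypothesis.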

How the results depend on the processing

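The actin covariate was chosen after the data were seen, and the other settings before. All 70 named genes past the threshold kept their direction under each setting in which they were tested, and 12 passed in all of those. Counts stayed within 1.5 times of 560 changed probe sets (220 higher, 340 lower, 457 by 1.5-fold) with no rescaling, quantile normalization, median centring, a pseudocount, a higher floor, the stricter filter, robust variance and array weights (824). With no filter 309 changed (131 higher, 178 lower, 235 by 1.5-fold), among more probe sets tested. Without cross-hybridising probe sets 261 did (95, 166 and 218), among fewer tested. With no intensity trend 333 did (124 higher, 209 lower). With the replicate block 290 did (99, 191 and 284). Same-numbered arrays did not deviate together (correlations of 0.063, -0.086, 0.012 and -0.2), which gives no sign of pairing by number but cannot exclude it. With the actin covariate 35 did (24 higher, 11 lower, 35 by 1.5-fold), with wider errors. Leaving out 1 array gave 240 to 695 changed, 100 to 315 higher, 140 to 380 lower and 225 to 586 by 1.5-fold, with fewer arrays but for the 695 without vehicle replicate 2, whose cause was not tested. Against 8 lists past the threshold, 0 passed with an estimated correlation, where the cause was not tested, and 5 to 10 of all lists, not always the same ones, under the other settings. The robust variance has no list test. With quantile normalization Hpx reversed to -0.28 (adjusted p = 0.0222) and the hepatocyte secreted protein list to -0.15 (adjusted p = 0.00297), and the cause was not tested. Named genes in settings other than leaving out an array gave the same call in 843 cases, a weaker one in 142 and a stronger one in 3. Signals near background limit the dimmest probe sets, whose changes the floor understates.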

Other observations

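The 4 gene families below, and their tests, were chosen after the data were seen.

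Of 28 complement and coagulation genes tested, 10 were lower and none higher in the limma fit, with a median log2 fold change of -0.40. The family had a camera p of 1.11e-07 with the preset correlation and 0.0896 with an estimated correlation (0.132 adjusted over the 4 families). C1s and C1r, the proteases that start the classical complement pathway, had log2 fold changes of -1.30 ± 0.20 (SE, adjusted p = 0.00345) and -0.83 ± 0.16 (adjusted p = 0.0125), and the inhibitor gene Serping1 had -0.64 ± 0.17 (adjusted p = 0.0399). The terminal component C9 was also lower, at -0.81 ± 0.15, as was the C4b-binding protein chain C4bpb at -0.94 ± 0.15. Of its 10 lower members, Fgb and F10 stand in lists already described and C1qb is a macrophage marker, and the macrophage list had a median of -0.76. A coordinate fall of hepatic complement and coagulation transcripts may lie behind this and is a hypothesis found and tested on the same arrays.

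Genes of antigen presentation and those regulated by interferon, with the macrophage list left out, included 4 lower and none higher of 31, with a median of -0.20 and a camera p of 0.0134 (0.0987 with an estimated correlation, 0.132 adjusted over the 4 families). The macrophage markers fell in the same arrays, among them the class II invariant chain Cd74 at -1.42, and leaving out their list does not remove what those cells contribute. The class II gene RT1-Db1 had a log2 fold change of -0.98 ± 0.23 (adjusted p = 0.0271) and the interferon-induced gene Ifitm3 -0.79 ± 0.14 (adjusted p = 0.00725). Alcohol and aldehyde dehydrogenases included 4 higher and none lower of 12, with Aldh1l1 at 1.26 ± 0.11 (adjusted p = 8.21e-05) and Adh4 at 1.31 ± 0.25 (adjusted p = 0.0108) beside Aldh1a1 and Adh1c. That family had a median of 0.24 and a camera p of 0.0112 (0.0454 with an estimated correlation, 0.132 adjusted over the 4 families). Translation elongation and initiation factors did not pass as a family. Their median was -0.11 over 24 genes, the camera p was 0.631, and Rack1, a protein bound to ribosomes, was the single member that passed, at 0.74 ± 0.10 (adjusted p = 0.00158).

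The count of changed probe sets was tested with a test set before the data were examined. Of the 35 splits of the 8 arrays into 4 and 4, 1 gave as many as 560, the real one, and the highest of the other splits gave 1.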
